A study of Mus musculus with 4 samples.

How the data were processed

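The data are 4 tables, 1 per library, from CD4+ T cells of mice cultured for 3 days under Th9 conditions, with 2 libraries from wild-type mice and 2 from mice that lack Bfar in T cells. Genotype was taken from the labels. RNA was sequenced on an Illumina HiSeq instrument, per the labels' protocols. Bowtie and RSEM are named, without versions, in the submitters' processing notes, which also name the genome build GRCm38 (mm10). RSEM assigns reads that match several transcripts by expectation maximisation, so its output is an estimated count that need not be whole. Per the file headers, each deposited table gives for every gene an expected count, an FPKM value and a length. The deposited FPKM values were made by the authors by dividing by transcript length and depth. Any steps before alignment, the strand setting and the annotation release are not given in the sources used here.

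The lowest FPKM listed was 0.01 in each table, and a gene missing from a table was treated as 0 there. In all 17478 genes were listed in at least 1 library and 14469 in all 4. The libraries held between 19058009 and 19782923 expected counts, and 3 counts in a library correspond to 0.152 to 0.157 CPM. No 2 libraries were duplicates: the chi-square per degree of freedom over genes was 2.21 between the wild-type libraries, 2.55 between the knockout libraries, and 14.2 to 17.6 across genotypes. Gene symbols are those in the tables. Coordinates were taken from the RefSeq gene table of GRCm38, in which 17440 gene identifiers matched.

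Expected counts were rounded to whole numbers and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, two-sided, with genotype as the factor, TMM normalization, the default filterByExpr filter (minimum count 10, minimum total 15) and Benjamini-Hochberg adjustment at 0.05. The filter kept 12677 genes. TMM factors lay between 0.997 and 1.0022, and the common biological coefficient of variation was 2.9%. The standard error of a log2 fold change was its absolute value divided by the square root of F. CPM values use TMM-scaled library sizes, and means are given ± SD over 2 libraries. With 2 libraries per group, a permutation of single values could not reach 0.05.

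Before the data were examined, 36 gene lists were written down. The 29 with at least 5 tested members were tested with camera (limma 3.58.1), which compares a list with other genes, with a preset inter-gene correlation of 0.01 and adjustment over the 29 lists. The lists of mast cell, natural killer and innate lymphoid, mitochondrially encoded, erythroid, sex-linked, CD8 and gamma-delta, and monocyte genes had fewer tested members and were not tested; levels of abundant members are given instead, except that no mitochondrially encoded gene is listed. Of the 29 tested lists, 12 passed. With an estimated correlation none passed (0 of 29 at the adjusted threshold), while fry called 16. In simulated data with 12677 genes, the Th2 list was raised by 1.2-fold. Camera with the preset correlation called it (adjusted p = 1.1e-41) and camera with an estimated correlation did not (adjusted p = 0.13). With 4 libraries the estimated version thus missed a change that was present. The data were simulated a single time, so its power was not measured. The simulated genes were drawn independently, so the simulation cannot show which correlation suits the real data. There the estimates were 0.44 for the glycolysis and hypoxia list, 0.41 for the integrated stress response list and 0.23 for the Th2 list. The preset version also called 1 other list. Several lists share members with the Th2 list, Gata3 among them, so this need not be a false call. fry asks whether a list's genes move, on balance, one way, and does not compare them with other genes. In simulated counts drawn from the real means, edgeR recovered 79% of genes changed by 1.5-fold and 85% of genes changed by 2-fold in this comparison over 12677 genes, and called 11 unchanged genes. DESeq2 recovered 67% and 71% and called 2.

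Genes named in the text follow a rule fixed before the data were examined: 11 genes of interest, the 10 largest rises and 10 largest falls among genes past the threshold with a mean of at least 5 CPM and groups that do not overlap, up to 4 members of each list with the smallest adjusted p, and the most abundant markers of other cells. Ms4a1, Rps2, Ubb, Serbp1, Rnaset2a, Borcs8, Ankrd33b, Bst2, Zbtb46, Itgax and Cd86 were named after their values were seen. A few genes that the rule names are not reported here.

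Near-identical copies were found by comparing the 31-mers of GENCODE M21 transcripts of the listed genes, which gave a sequence for 17243 of them. A gene counts as having a copy if at least 20% of its 31-mers occur in another listed gene, or if it is the best partner of a gene that shares at least 50% of its 31-mers with it. The partner clause was added after the data were seen, because Atp6v0c shares only 11.9% of its 31-mers and missed the first rule although its copy Atp6v0c-ps2 moved opposite to it. Some genes meet the rule because their annotated transcripts overlap those of a neighbour, as Il12rb2 and Serbp1 do; pairs within 10000 bases of each other were left out of the tests on pairs of copies. The first rule alone gives 1559 genes and the wider rule 1717. Under the first rule alone, 13 of the large changes had a copy (21.7%, against 7.8% of tested genes), and under the wider rule 14 (23.3%, against 9%).

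Alternatives planned before the data were examined were the replicate number as a block, RLE, upper-quartile and no composition factors, other filters on low counts, DESeq2 1.42.0, limma-voom, limma on log2(FPKM + 0.1) and log2(FPKM + 1), a minimum fold of 1.5, truncated counts, a robust dispersion prior, and each replicate left out in turn. After the data were seen, removal of per-library lowess trends (span 0.3) on GC content and length, and leaving out genes with copies under both rules, were added. A first version of the trend removal gave far more falls than rises. A centring of each library's correction was added, the imbalance stayed, and its source was then found to be library offsets applied to the wrong entries. That fault was corrected, the centring was kept, and only the corrected version is reported. The tests on pairs of copies were revised after a first version had given its results. The neighbours were left out, which moved the median net over gross change from 0.086 to 0.087. The test on risen copies was first run on pairs called in opposite directions, then on all pairs whose copy rose, and is now decided on the former with both results given, and what it should show was rewritten to match after both had been seen. The random fold was given to the more abundant member of each pair, since a near-silent copy cannot balance its partner; given to the partner as first listed it yields a random median of 0.653. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used for joins, resampling and figures. Mitochondrially encoded genes are not listed in the tables used here, so their share was not examined.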

Results

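Gene expression was measured by RNA sequencing in mouse CD4+ T cells that had been sorted as naive cells from spleen and lymph nodes, activated through CD3 and CD28, and cultured for 3 days under Th9 conditions. Th9 cells are helper T cells that secrete interleukin 9. The mice were C57BL/6, aged 6 to 8 weeks, and were either wild type or lacked Bfar in T cells. Each genotype had 2 libraries, 4 in all. The summed expected counts were 19782923 and 19736182 in the wild-type libraries and 19321076 and 19058009 in the knockout libraries, so depth hardly differed between the genotypes. The most abundant gene, the translation elongation factor Eef1a1, took 1.11% to 1.24% of the counts. The labels do not say that the replicates came from separate mice, so p-values measure only the spread between these samples, which may be technical. No batch is named in the labels, and a batch that followed genotype could not be told apart from it.

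The first question was whether the knockout label holds in each library. Bfar (gene 67118, chromosome 16, 13671858 to 13703612, GRCm38) encodes a RING-type ubiquitin ligase of the endoplasmic reticulum. It had 36.4 and 32.9 CPM (counts scaled to library size) in the wild-type libraries and 8.45 and 7.79 in the knockout libraries, so both knockout libraries matched their label. Its log2 fold change, knockout over wild type, was -2.09 ± 0.09 (SE, n = 2 per group; edgeR adjusted p = 5.38e-10). The deleted exons are not given in the sources used here, and reads from kept exons can remain in a gene-level count.

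Il9, the cytokine that defines the culture (gene 16198, chromosome 13, 56479277 to 56482257), was lower in both knockout libraries. Its level fell from 520.8 ± 22.4 to 254.1 ± 22.9 CPM (SD, n = 2), a log2 fold change of -1.04 ± 0.05 (SE; edgeR adjusted p = 1.89e-09). In the deposited FPKM values the means were 1026 and 499.

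Of the other genes fixed for reporting in advance, few differed much. Tgfbr1, the type I TGF-beta receptor, had a log2 fold change of -0.02 ± 0.04 (edgeR adjusted p = 0.812), and 0.03 without knockout replicate 2. Tgfbr2, the type II receptor, had 0.14 ± 0.04 (SE), with an edgeR adjusted p of 0.0227 that rose to between 0.0662 and 0.151 when any 1 library was left out, to 0.191 in DESeq2, to 0.0707 with no filter on low counts, to 0.0866 with log2(FPKM + 0.1), to 0.0865 with log2(FPKM + 1) and to 0.055 after removal of GC and length trends. Smad7, an inhibitor of the pathway, had 0.16 ± 0.06 (adjusted p = 0.0567), and 0.24 (adjusted p = 0.023) without wild type replicate 2. Its adjusted p was 0.0445 with upper-quartile factors and 0.0495 among genes with a mean of at least 1 CPM. Irf4, a transcription factor required for Th9 cells, had 0.08 ± 0.03 (adjusted p = 0.1). Gata3, the Th2 regulator, rose by 0.14 ± 0.04 (adjusted p = 0.0155), which was lost without wild type replicate 2 (0.133) or knockout replicate 2 (0.174), with no filter on low counts (0.0755), and with log2(FPKM + 0.1) (0.073) or log2(FPKM + 1) (0.0708). Foxp3, the regulatory T cell factor, rose from 309.5 ± 15.8 to 359.2 ± 16.8 CPM (log2 0.21 ± 0.04, adjusted p = 0.00217), with an adjusted p of 0.0805 without knockout replicate 1, 0.0508 with no filter and 0.0502 with log2(FPKM + 0.1). Il10 had 0.11 ± 0.11 (adjusted p = 0.484), and -0.03 without knockout replicate 2. Ifng was near the detection limit, with 10, 20, 39 and 37 counts in wild type 1 and 2 and knockout 1 and 2. It rose by 1.38 ± 0.33 on the log2 scale (edgeR adjusted p = 0.0059), and its adjusted p was 0.0983 without wild type replicate 1, 0.0747 without knockout replicate 1, 0.0758 without knockout replicate 2, 0.0527 with no filter and 0.0941 in DESeq2. With unfiltered FPKM, Tgfbr2 (0.132), Gata3 (0.149), Foxp3 (0.144) and Ifng (0.136) did not pass either. Spi1, which encodes PU.1, had between 1 and 5 counts per library and was too low to test.

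**Figure D1:**
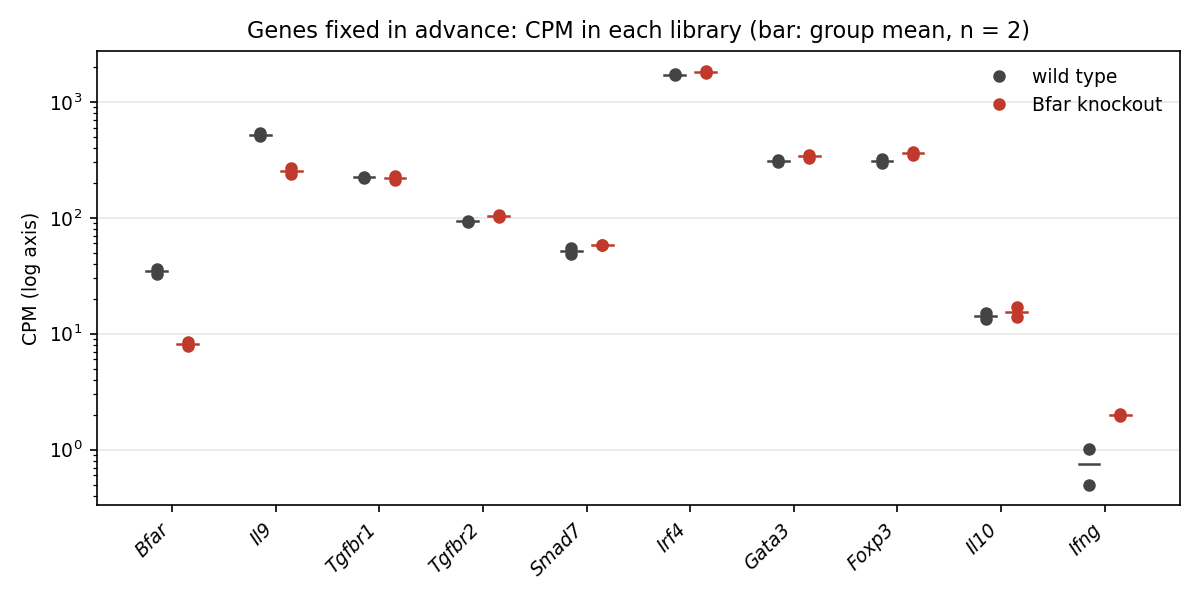
CPM (log axis) of 10 genes fixed in advance, with 1 point per library and a bar at each group mean (n = 2); Spi1 was too low to test. Bfar and Il9 are lower in both knockout libraries, with means of 8.12 against 34.7 CPM and 254.1 against 520.8 CPM, while Tgfbr1 overlaps between the genotypes.

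Across the transcriptome, 3398 of 12677 tested genes changed in the knockout, 1728 upward and 1670 downward. Most changes were small, with a median fold of 1.2 among called genes. Among genes with a mean of at least 5 CPM, 44 rose and 17 fell by at least 2-fold. The 2 groups did not overlap for 63.5% of tested genes, where chance gives 33.3%. The count was 1441 without knockout replicate 2, 1894 without knockout replicate 1 and 2139 without wild type replicate 1. It was 1569 with DESeq2, 1928 with no filter on low counts, 2139 with log2(FPKM + 0.1), 2171 with log2(FPKM + 1), 259 with unfiltered FPKM, and 138 when tested against a fold of 1.5. Without wild type replicate 2 the count of lower genes was 1112.

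Among the largest changes in genes without a near-identical copy, Rab6b, a small GTPase of vesicle transport, fell from 12.3 ± 0.475 to 0.914 ± 0.0267 CPM (log2 -3.74 ± 0.17, SE; edgeR adjusted p = 9.52e-10). Inppl1, which encodes the inositol phosphatase SHIP2, fell from 65.0 ± 2.99 to 22.0 ± 0.69 CPM (log2 -1.56). The zinc finger gene Zfp868 fell by 1.25 on the log2 scale, and so did Ubxn11. Vwa1, an extracellular matrix protein, rose from 0.834 ± 0.177 to 15.4 ± 1.72 CPM (18.4-fold, adjusted p = 5.05e-10). Ramp3, a partner of calcitonin-family receptors, rose by 2.62 ± 0.17, the phosphodiesterase gene Gdpd3 by 2.17 ± 0.14, and the inhibitory receptor gene Havcr2, which encodes TIM-3, by 2.14 ± 0.21 (adjusted p = 2.72e-06), from 2.20 to 9.67 CPM.

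Besides Bfar, the other genes named among the 10 largest rises and 10 largest falls can share reads with a near-identical copy, and their individual values are uncertain. Eno1b, a copy of the enolase gene Eno1, went from 2.22 and 1.42 to 761.7 and 836.1 CPM, while Eno1 fell from 4088 to 3069 CPM. Atp6v0c-ps2 went from 4.09 to 144 CPM, while Atp6v0c, a proton pump subunit, fell from 209.5 to 60.3 CPM. The sums of these pairs changed far less, by -0.08 and -0.06 on the log2 scale. Hmga1, a chromatin protein gene, fell from 345 to 39.2 CPM. Gm10653, a copy of the ribosomal protein gene Rps2, rose from 2.07 to 107.5 CPM, Gm1821, a copy of Ubb, from 1.97 to 10.4 CPM, and LOC101056073 from 0.202 to 11.7 CPM. Tmem181b-ps fell from 45.6 to 6.06 CPM and Rnaset2b from 29 to 6.77 CPM. Tmem254b, with 11.7 and 44.6 CPM in the wild-type libraries, passed the edgeR test (adjusted p = 0.00919) but not without wild type replicate 2 (0.241), knockout replicate 1 (0.137) or knockout replicate 2 (0.287), nor in DESeq2 (0.306), limma-voom (0.0556), with no filter (0.19), or with log2(FPKM + 0.1) (0.174) or log2(FPKM + 1) (0.175). Of the 60 genes with a mean of at least 5 CPM, a change of at least 2-fold and a known transcript sequence, 23.3% shared sequence with a near-identical copy or an overlapping neighbour, against 9% of all tested genes.

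**Figure D2:**
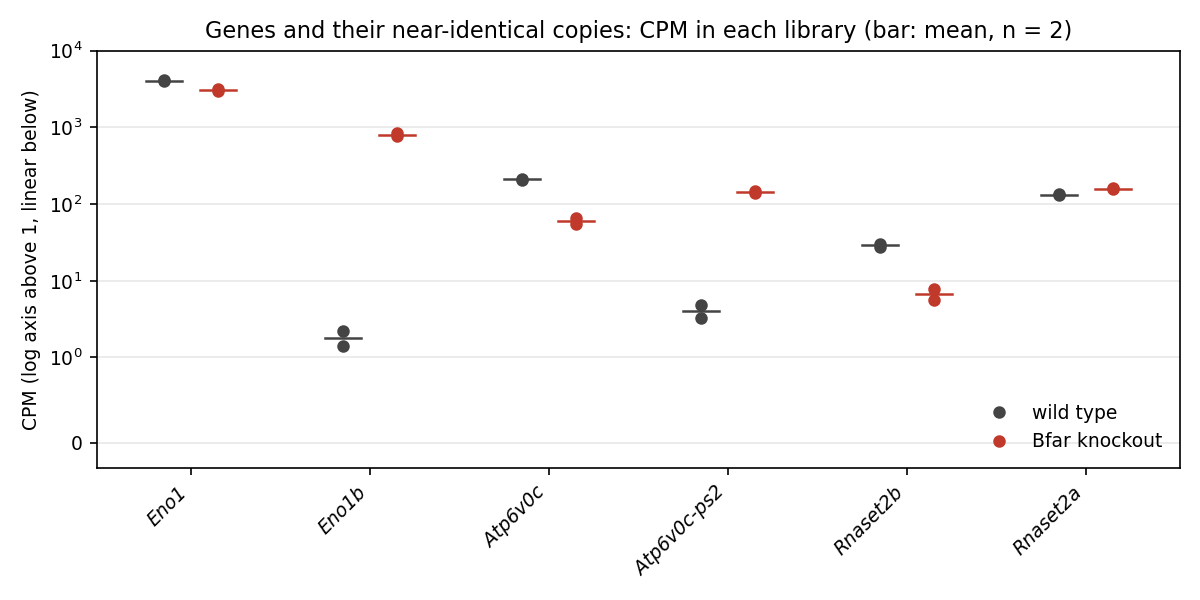
CPM of 3 genes and their near-identical copies, with 1 point per library and a bar at each group mean (n = 2); the axis is logarithmic above 1 and linear below. In each pair 1 member is higher and the other lower in both knockout libraries, as for Atp6v0c (209.5 to 60.3 CPM) and Atp6v0c-ps2 (4.09 to 144 CPM).

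Gene lists written down in advance were then examined. Il9 led the list of Th9 cytokines and regulators, of which 7 of 22 tested members fell and 3 rose (7 and 5 adjusted over the list alone). The list did not stand apart from other genes (camera adjusted p = 0.2). Ccl20, a chemokine of helper T cells, fell from 13.6 ± 0.885 to 7.05 ± 0.512 CPM (log2 -0.94 ± 0.11, edgeR adjusted p = 2.91e-05), while Tnfrsf18, which encodes the costimulatory receptor GITR, rose by 0.30 ± 0.04. Irf8 fell by 0.19 (adjusted p = 0.00365), with an adjusted p of 0.0958 without knockout replicate 2 and 0.0551 with no filter on low counts.

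In lists of the TGF-beta pathway, which is needed for Th9 cultures, more members rose than fell, though neither list passed camera. Of 25 receptors and SMAD pathway members 8 rose and 1 fell (10 and 1 adjusted over the list alone; camera adjusted p = 0.054, 0.041 without wild type replicate 2, 0.019 with no filter on low counts, 0.031 with copies left out, and 0.35 with an estimated correlation). Tgfb3, a TGF-beta ligand, rose from 7.03 ± 1.09 to 19.7 ± 0.96 CPM (log2 1.49 ± 0.11), the activin receptor gene Acvr2a by 0.45 ± 0.09 and Bmpr2 by 0.25 ± 0.04. Of 21 genes known to be induced by TGF-beta, 9 rose and 2 fell (11 and 2 adjusted over the list alone; camera adjusted p = 0.055, 0.012 with no filter, and 0.35 with an estimated correlation). By fry, the adjusted p was 0.015 for both lists. The lists share members, Smad7 and Tgfbr1 among them, so they are not separate results. The transcription factor gene Bhlhe40 rose by 0.37 ± 0.04 on the log2 scale (edgeR adjusted p = 1.82e-06) and Vim, which encodes vimentin, by 0.28 ± 0.04, whereas Il9, also among the genes induced by TGF-beta, fell.

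Of 18 genes known to be repressed by TGF-beta, 6 rose and 5 fell (7 and 5 adjusted over the list alone). The camera adjusted p was 0.021, and the adjusted p = 0.35 with an estimated correlation. Fasl, the death receptor ligand, rose by 0.89 ± 0.07, the granzyme gene Gzmb by 1.02 ± 0.09 and Stat4 by 0.79 ± 0.07 on the log2 scale. Il12rb2, the interleukin 12 receptor chain, had a log2 fold change of 1.99 ± 0.08, but its annotated transcripts overlap those of its neighbour Serbp1 and the value is uncertain. The Th1 list, with 8 of 19 members up and 5 down (8 and 5 adjusted over the list alone), holds Il12rb2 and Stat4 as well. Its camera adjusted p was 0.022, and the adjusted p = 0.35 with an estimated correlation. Runx3 rose by 0.42, while the cytokine gene Lta fell by 0.41 ± 0.04. Both lists lost their call when genes with copies were left out (adjusted p = 0.33 for each), and both without knockout replicate 1 (0.055 for each). The list of TGF-beta-repressed genes also lost it without knockout replicate 2 (0.071), and with no filter on low counts the values were 0.42 and 0.34.

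Of 16 Th2 genes 7 rose and 1 fell (9 and 1 adjusted over the list alone; camera adjusted p = 0.0035). The adjusted p = 0.38 with an estimated correlation, and fry gave 0.064. Il24 rose by 1.02 ± 0.05 on the log2 scale (edgeR adjusted p = 7.65e-10), the hypoxia-responsive factor Epas1 rose by 0.66 ± 0.10, and the cytokine gene Il3 rose from 3.87 ± 1.39 to 8.90 ± 0.528 CPM. The Th17 list went both ways, with 4 of 19 members up and 5 down (4 and 5 adjusted over the list alone; camera adjusted p = 0.34, direction down, as the mean, with a median just above 0). The membrane protein genes Tmem176b and Tmem176a fell by 0.98 ± 0.06 and 0.92 ± 0.06, while Stat3 rose by 0.43 ± 0.04 and Rora by 0.47 ± 0.05.

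Of 20 genes of regulatory T cells 12 rose and 2 fell (14 and 3 adjusted over the list alone; camera adjusted p = 2.2e-05). The adjusted p = 0.35 with an estimated correlation. Ctla4 rose from 325 ± 12.8 to 536 ± 27.2 CPM (log2 0.72 ± 0.04, edgeR adjusted p = 1.52e-08), Tnfrsf9 by 0.58 ± 0.04, Tigit by 0.97 ± 0.09 and Ikzf4 by 0.30 ± 0.04. Inhibitory receptors overlap with that list. Of these, 7 of 14 rose and 2 fell (8 and 2 adjusted over the list alone; camera adjusted p = 0.00077), with an adjusted p = 0.35 with an estimated correlation. Besides Ctla4, Tigit and Havcr2, Lag3 rose from 78 ± 3.77 to 116.5 ± 0.689 CPM. Of 9 cytotoxic effector genes 5 rose and none fell (6 and 0 adjusted over the list alone; camera adjusted p = 0.001), and the adjusted p = 0.35 with an estimated correlation. Gzmb and Fasl about doubled in CPM, from 22.9 to 46.6 and from 18.9 to 35.2, and Tnfsf10, which encodes TRAIL, rose by 0.32 ± 0.05.

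Of 21 genes of naive and central memory T cells 12 rose and 1 fell (12 and 1 adjusted over the list alone; camera adjusted p = 1.5e-07). The adjusted p = 0.35 with an estimated correlation. Il7r, the survival receptor of resting T cells, rose from 12.6 ± 0.332 to 32.5 ± 0.439 CPM (log2 1.36 ± 0.08, edgeR adjusted p = 1.26e-08). The lymph node homing receptor gene Ccr7 rose by 0.85 ± 0.04, Txnip by 0.73 ± 0.06 and Satb1 by 0.46 ± 0.04. T cell activation genes split, with 8 of 26 up and 9 down (10 and 10 adjusted over the list alone; camera adjusted p = 0.7, with a negative median and mean and an upward test direction that turned without knockout replicate 1, adjusted p = 0.49). Dusp5 rose by 0.59 and Nr4a2 by 0.86, while the amino acid transporter gene Slc7a5 fell by 0.35. Chemokines and their receptors also split, with 5 of 17 up and 4 down (7 and 4 adjusted over the list alone). The camera adjusted p was 0.081, 0.048 after removal of GC and length trends and 0.38 with an estimated correlation, and fry gave 0.053. Cxcr4 rose by 1.11 ± 0.08, Cx3cr1 by 0.82 ± 0.08 and Cxcr6 by 1.02 ± 0.12. The median of that list was -0.06 although its test direction was upward.

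Lists of metabolic genes differed in direction. Of 31 glycolysis and hypoxia genes 17 rose and 1 fell (20 and 1 adjusted over the list alone; camera adjusted p = 1.5e-10). The adjusted p = 0.35 with an estimated correlation. The glucose transporter gene Slc2a3 rose from 234.5 ± 9.63 to 476.9 ± 4.42 CPM (log2 1.02 ± 0.04, edgeR adjusted p = 9.96e-11), Ndrg1 by 0.99 ± 0.04 and the oxidase gene Ero1l by 0.51 ± 0.03. The member that fell was Eno1, whose value is uncertain because of Eno1b. Of 26 genes of the integrated stress response and amino acid synthesis, 20 fell and 2 rose (21 and 2 adjusted over the list alone; camera adjusted p = 3.2e-09). The adjusted p = 0.35 with an estimated correlation, and fry gave 0.053. Shmt2, of mitochondrial serine metabolism, fell by 0.38 ± 0.03, the serine synthesis gene Psph by 0.39 ± 0.04 and Chac1, which degrades glutathione, by 0.66 ± 0.07 on the log2 scale. Vldlr, a lipoprotein receptor gene, rose by 0.46 ± 0.04. Of 39 oxidative phosphorylation genes 3 fell and none rose (0 and 0 adjusted over the list alone), and the camera adjusted p was 0.061. With no filter on low counts it was 0.0028 and with copies left out 0.048. With an estimated correlation it was 0.38, after removal of GC and length trends 0.25, and fry gave 0.088. Of 23 cholesterol synthesis genes 9 fell and 1 rose (10 and 1 adjusted over the list alone), and the camera adjusted p was 0.055. It was 0.0066 with no filter, 0.041 with copies left out and 0.048 after removal of GC and length trends. With an estimated correlation it was 0.35, and fry gave 0.023. Dhcr7 fell by 0.24 ± 0.04 and Fdft1 by 0.20 ± 0.04, while the sterol carrier gene Stard4 rose by 0.28 ± 0.04.

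**Figure D3:**
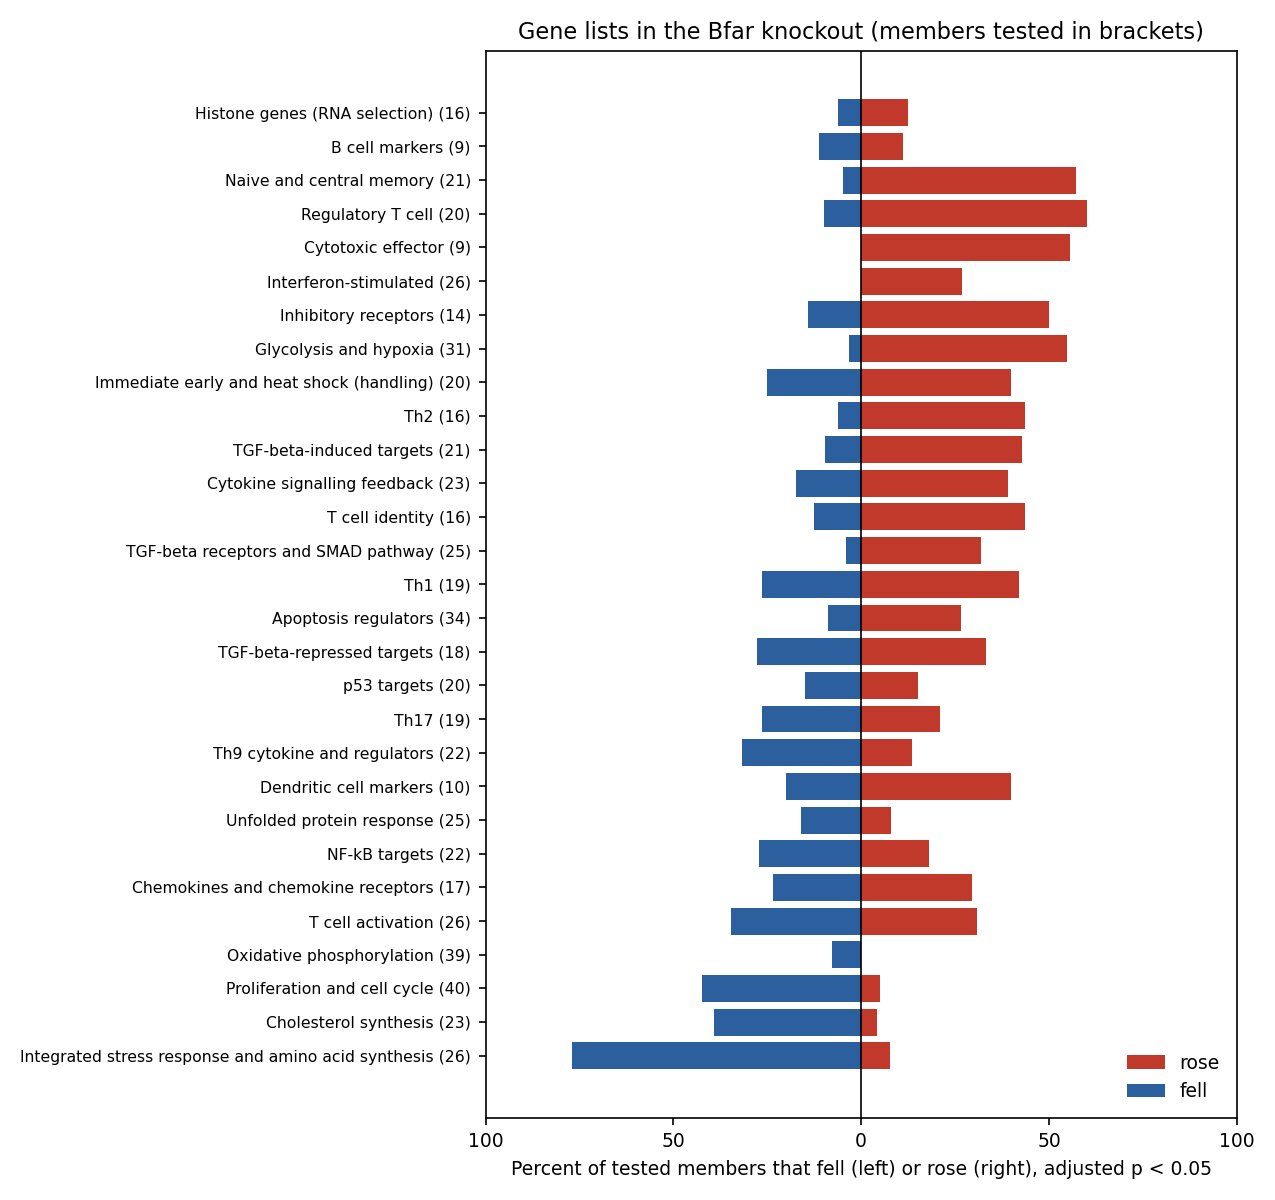
Percent of the tested members of each of 29 gene lists that fell (bars to the left) or rose (bars to the right) in the knockout at an edgeR adjusted p below 0.05, sorted by median log2 fold change; the number tested is in brackets. The integrated stress response list has 20 of 26 members down, and the glycolysis and hypoxia list has 17 of 31 up.

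Of 40 cell cycle genes 17 fell and 2 rose (19 and 2 adjusted over the list alone; camera adjusted p = 0.001), and the adjusted p = 0.35 with an estimated correlation. Ccne1, which encodes the G1/S cyclin E1, fell by 0.46 ± 0.05, the mitotic kinase gene Plk1 by 0.30 ± 0.04, Cdc20 by 0.26 ± 0.04 and Mcm2, of the replicative helicase, by 0.23 ± 0.04. Of 26 interferon-stimulated genes 7 rose and none fell (9 and 0 adjusted over the list alone; camera adjusted p = 0.0087), and the adjusted p = 0.35 with an estimated correlation. Usp18 rose from 12.9 ± 0.634 to 25.0 ± 1.87 CPM, Gbp5 by 1.09 ± 0.14 on the log2 scale and Stat2 by 0.39 ± 0.05. Of 23 cytokine signalling feedback genes 9 rose and 4 fell (12 and 5 adjusted over the list alone; camera adjusted p = 0.014), and the adjusted p = 0.35 with an estimated correlation. Lif rose by 0.55 ± 0.05, Socs3 by 0.49 ± 0.05 and the survival gene Bcl2 by 0.34 ± 0.04.

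**Figure D4:**
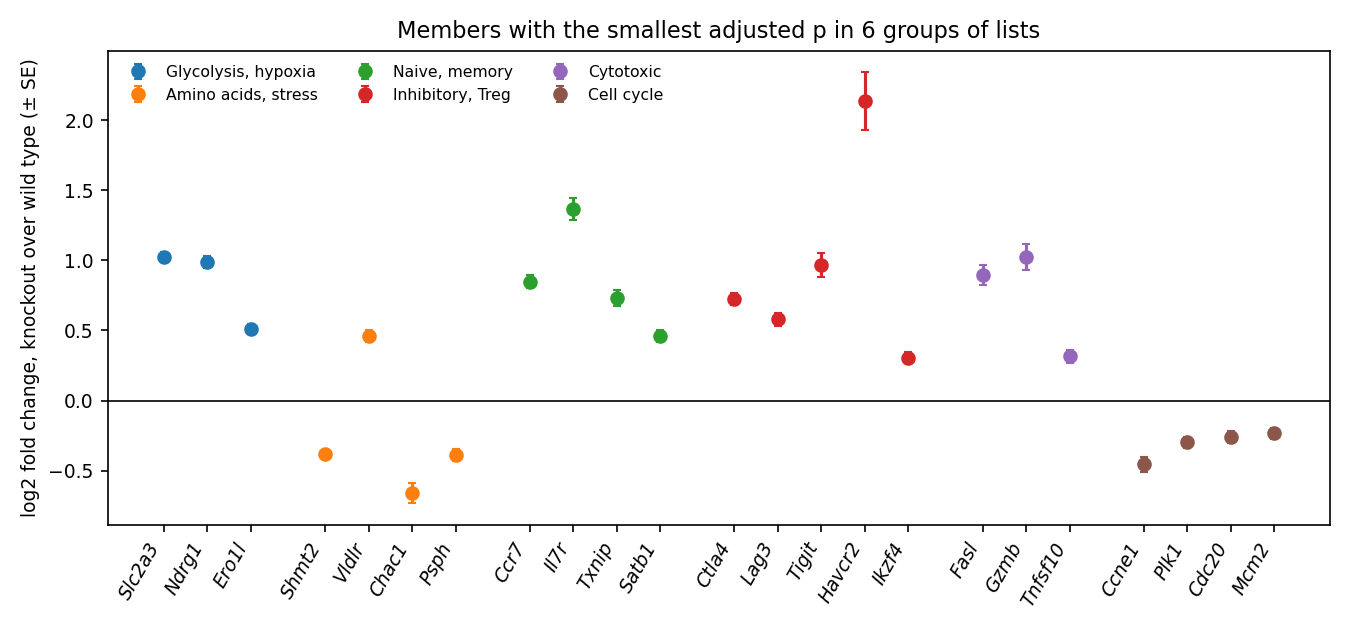
Log2 fold change, knockout over wild type, with its standard error (n = 2 per group), for members with small adjusted p of the glycolysis, stress response, naive and memory, inhibitory and regulatory, cytotoxic and cell cycle lists. Among the genes drawn, Havcr2 (2.14) and Il7r (1.36) are highest and Chac1 (-0.66) is lowest.

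The remaining lists did not stand apart from other genes in camera. Apoptosis regulators had 9 of 34 members up and 3 down (adjusted p = 0.2, and 0.015 by fry), with Bnip3 up by 0.44 and Bcl2l1 down by 0.21. The unfolded protein response had 2 of 25 up and 4 down (adjusted p = 0.53), with Edem1 up by 0.32 and the chaperone gene Hspa5 down by 0.17. The p53 targets had 3 of 20 up and 3 down (adjusted p = 0.82), and the NF-kB targets 4 of 22 up and 6 down (adjusted p = 0.34, and 0.015 by fry), with Tnfaip3 up by 0.31 and Tnf down by 0.34. Adjusted over the list alone, the counts up and down were 9 and 5, 2 and 4, 4 and 5, and 4 and 6. The unfolded protein response had a median of -0.02, a mean of 0.01 and a downward test direction, and the p53 targets a median of 0.01, a mean of -0.03 and a downward test direction.

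Markers of other cells and of sample handling were compared in the same way. T cell identity genes had 7 of 16 members up and 2 down (8 and 4 adjusted over the list alone), with Cd28 up by 0.34 and Cd6 down by 0.29. The camera adjusted p was 0.11, 0.048 after removal of GC and length trends and 0.37 with an estimated correlation, and fry gave 0.036. B cell markers had 1 of 9 up and 1 down (1 and 1 adjusted over the list alone; camera adjusted p = 0.7, direction up, and down without wild type replicate 1, 0.97). H2-Ab1 rose from 69 to 85.1 CPM and Cd74 fell from 106.4 to 86.9. Ebf1 was at 3.92 and 4.78 CPM in wild type and knockout, and Cd79b at 4.6 and 3.34. Ms4a1, with means of 0.0758 and 0.0527 CPM, was too low to test. Dendritic cell markers had 4 of 10 up and 2 down (5 and 3 adjusted over the list alone). The camera adjusted p was 0.16, direction up, with a median of -0.01 and a mean of 0.06. The most abundant ones, Irf8 and Ccr7, are also T cell genes. Batf3 was at 56.7 and 49.9 CPM in wild type and knockout, Cst3 at 47.3 and 52.8 and Bst2 at 22.8 and 26.6. Of the less abundant ones, Xcr1 rose from 1.1 to 2.52 CPM and Cd80 from 4.57 to 6.97 CPM. Neither Xcr1 nor Cd80 passed in DESeq2 (adjusted p = 0.0899 and 0.124). Lower means in the knockout were seen for Zbtb46 (2.78 and 2.27 CPM), Itgax (1.26 and 0.647) and Cd86 (0.834 and 0.469). The most abundant markers of monocytes, macrophages and neutrophils were Ctss, at 29.6 and 29.2 CPM in wild type and knockout, and Apoe, at 5.05 and 5.23 CPM. In the list of CD8 and gamma-delta T cells, Runx3 was at 187 and 251 CPM and Cd8b1 at 9.63 and 9.03. In the list of natural killer and innate lymphoid cells, Rora was at 98.2 and 136 CPM, Il7r at 12.6 and 32.6 and Eomes at 3.31 and 2.53, and Runx3, Rora and Il7r are also T cell genes. The mast cell receptor gene Kit was at 1.41 and 3.45 CPM, and the erythroid gene Epor at 2.55 and 2.3. The Y-linked genes Eif2s3y and Ddx3y were expressed in all 4 libraries, and Xist was below 0.5 CPM in each. Immediate early and heat shock genes had 8 of 20 members up and 5 down (8 and 6 adjusted over the list alone; camera adjusted p = 0.53), with Btg2 up by 0.50 and Junb by 0.18. Replication-dependent histone genes, which mark how RNA was selected, had 2 of 16 up and 1 down (2 and 1 adjusted over the list alone; camera adjusted p = 0.7, direction up, and down without knockout replicate 2, 0.77), with Hist1h2ap down from 205 to 151.5 CPM, a gene with near-identical copies.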

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

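The comparison of transcript lengths was chosen after the data were seen. The tables give an expected transcript length per gene, which moves when the use of isoforms differs. For each of 9891 genes with a mean of at least 5 CPM, the gap between the 2 genotypes, taken between their nearest libraries, was compared with the gaps in the 2 other ways of splitting the 4 libraries into pairs. The largest gap in those other splits was 13.83% of the mean length. Borcs8 exceeded it, with lengths of 1497 and 1544 bases in wild type and 2011 and 2012 in the knockout, a gap of 26.45%. Ankrd33b did so barely, with 4608 and 5235 against 6001 and 6301 bases, a gap of 13.84%. No explanation was tested for either gene.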

How the results depend on the processing

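Leaving out genes with copies and removing GC and length trends were chosen after the data were seen; the other settings were planned. Bfar and Il9 kept their direction and their side of the threshold in all 16 alternatives run for each, with log2 fold changes of -2.16 to -2.02 and -1.13 to -0.94 when each library was left out. In those fits the lone library of a group is assumed to vary like the other group. The count of changed genes, 3398, ranged from 1441 to 2355 with 1 library left out (812 to 1243 higher, 629 to 1112 lower), which has fewer samples. It was 1928 (1051 higher, 877 lower) with no low-count filter, 1569 (839, 730) in DESeq2, 2139 (1019 higher) with log2(FPKM + 0.1), 2171 (1031 higher) with log2(FPKM + 1), 259 (143, 116) with unfiltered FPKM, and 138 (104, 34) against a fold minimum of 1.5, a stricter question. The cause was not tested for the others. With the replicate number as a block the count was 3952; the numbers do not pair the samples, since deviations of libraries with the same number correlated by 0.005 across genes, which are not independent replicates. With that block Irf4 (0.0494) and Smad7 (0.0246) had an adjusted p under the threshold. It was 3338 without copies (3408 by the narrower rule) and 3352 after trend removal, of which 2955 were shared.

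Of 125 other named genes, 102 kept their call and direction in every alternative run for them but unfiltered FPKM. With unfiltered FPKM, 75 of the 125 lost their call. Truncated counts, the robust dispersion prior, the fold minimum and leaving out copies were not compared gene by gene. Some of the 125 had no result in DESeq2, in the filtered FPKM fits or with the filter on mean CPM. With 1 library left out, Tgfbr1 ranged from -0.068 to 0.034, passing through 0 without wild type replicate 2, and Il10 from -0.031 to 0.246. Camera called 0 lists with an estimated correlation, against 12 with the preset one and 16 with fry. The T cell activation list turned direction without knockout replicate 1 (0.49; range 0.2 to 0.89) and with no low-count filter (0.91). The B cell list (0.97; range 0.46 to 0.97) turned without wild type replicate 1 and the histone list (0.77; range 0.77 to 0.97) without knockout replicate 2. The cause was not tested. Depth limits Ifng and Spi1, whose counts are low.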

Other observations

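All tests in this part were chosen after the result was seen.

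Several genes with a near-identical copy changed opposite to that copy, as Atp6v0c and Atp6v0c-ps2 did. A different division of reads between copies could account for the pairs called in opposite directions: over 4 of them the net change was a median of 0.087 of the gross change, against a median of 0.434 and a 5th percentile of 0.206 in random pairs. More transcription of the risen copies with the partner's output kept would not lower the partner. In 3 of the 7 pairs whose copy rose, the partner was lower, at an edgeR adjusted p of 3.64e-07 or less. The sums of those pairs did not rise (median -0.08 on the log2 scale). These values argue against that explanation for those 3 pairs only. The pairs were picked because their partner was called lower, so they are no separate test. The explanation stays open for the other 4. Over all 7, a difference of the sums from what the gain of the copies alone would give did not pass (exact sign-flip permutation p = 0.17). A candidate cause of a different division is a strain segment in 1 genotype, since 4 pairs of the 7 partner genes of risen copies lay within 5 Mb, against a mean of 0.33 in 10000 random sets (permutation p = 0.0012), Atp6v0c and Rps2 among them on chromosome 17. That test was devised after those positions had been noticed and after 12 other position tests whose smallest p was 0.13, the labels give C57BL/6 for all libraries, and the hypothesis stays open.

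Large changes also occurred in genes without a copy, such as Rab6b and Vwa1. Strain segments that each hold several of them are argued against as the source of most. Of 46 such genes 17.4% had another within 5 Mb, and the 4 pairs found were no more than the 6.1 in shuffled positions (permutation p = 0.82). The share depends on the window: it was 8.7% within 1 Mb and 54.3% within 20 Mb, with 15 pairs against 18.6 in shuffled positions at 20 Mb (permutation p = 0.79). Scattered segments with 1 large change each could not be seen in this way and stay open. A direct or indirect effect of losing Bfar, and a batch that goes with genotype, stay open for these genes and were not tested.

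In the glycolysis and hypoxia list 17 of 31 members rose and 1 fell, while in the integrated stress response list 20 of 26 fell and 2 rose. GC content and length trends as the whole cause are argued against, since after their removal the larger adjusted p of the 2 lists was 3.3e-08. Reads shared with copies are argued against in the same way, with 3.6e-10 when genes with copies were left out. Both values rest on the preset correlation of 0.01, against estimates of 0.44 and 0.41 for these lists. A culture or library batch that goes with genotype cannot be told apart from an effect of Bfar, as no label splits the samples another way, and with an estimated correlation the adjusted p was 0.35. The difference in genotype may be the source, but it shares its split of the libraries with any such batch.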
